A study of Drosophila melanogaster with 14 samples.

How the data were processed

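Small RNA was profiled in 14 libraries from Drosophila melanogaster embryos, 2 from each of 7 labelled stages. Per the labels' protocols, total RNA was extracted with TRIzol, 1 ng entered a modified Illumina TruSeq small RNA preparation, and libraries were amplified over 15 PCR cycles. The deposited table holds raw read counts per mature miRNA arm, whole numbers with a different total in each library. Per the submitters' processing notes, Bowtie and HTSeq were used with the genome build dm6, without versions. How reads matching several miRNA loci were counted, and the release of the miRNA annotation, are not given in the sources used here. Arms with near-identical relatives therefore have uncertain counts.

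Every column was matched to its library by the title in the labels. Stages and times came from the labels, which carry no replicate numbers, so replicates were numbered in accession order and nothing was paired. Total counts ran from 17462 to 72507 per library. A level of 3 counts was the floor for a count of 0, taken over the group on the TMM scale, and exact binomial intervals at 95% cover ratios of pooled counts. Such intervals leave out PCR duplication and differences between embryos. A fold given as at least a value sets the other group against the floor without its own counting error. It can therefore lie above the lower end of the interval.

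Counts were analysed in R 4.3.3 with edgeR 4.0.16. Of 466 arms, 215 had no count and 85 passed filterByExpr by stage; the 85 held at least 99.4% of the counts of each library. A quasi-likelihood model (TMM factors, 1 coefficient per stage, all 14 libraries, 7 residual degrees of freedom) gave the test among all stages, each step between neighbouring stages, stage 7 against stage 1, and the mean of stages 5 to 7 against that of stages 1 to 3. The threshold was a Benjamini-Hochberg adjusted p of 0.05 over the 85 arms. The standard error of a log2 fold change was derived from it and the F statistic. log2 CPM values used a prior count of 2. Lists were tested with fry in limma 3.58.1 on the same design, adjusted over the 11 lists with at least 2 tested arms, and with camera (preset correlation of 0.01, or estimated). Membership of bilaterian families was permuted 100000 times for the difference of medians.

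Each stage comparison was repeated with DESeq2 size factors, with library size only, without the filter, with a mean count of at least 50, with DESeq2 1.42.0, without each library in turn, and where it applied with the 2 stages alone or with stages 6 and 7 against 1 and 2. Where a library was left out, the remaining one of its stage was assumed to vary like the other stages. The comparisons, lists, alternatives and naming rule were written before the data were examined, with 1 exception in the lists. Members miR-iab-4 and miR-iab-8 of the Hox list had been spelled without their prefix and matched no arm, and the spelling was corrected after the data had been read. That added miR-iab-4-5p to the 3 other tested arms of the list. With the first spelling the adjusted p of the list was 7.57e-05, and all 11 lists passed either way. Further alternatives chosen after seeing the data were the removal of stage 4 replicate 1 and stage 7 replicate 2 together, thinning to the shallowest library, and removal of miR-286-3p.

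Named arms followed a rule. It took the 10 largest rises and 10 largest falls late against early with a mean of at least 100 CPM and no overlap of libraries, up to 3 in each direction per step, the 5 most abundant arms, 2 per peak stage and up to 4 per list. Arms named outside it are miR-305-3p and miR-305-5p, which complete a count of 3 falls, and miR-2b-2-5p and miR-2c-5p of the K-box list. The 3p arm of miR-124 and, among the other observations, bantam-5p, miR-8-5p and both arms of miR-34 are also outside it. These were chosen after their values were seen. Lists were written from general knowledge of fly miRNAs and name tissues where members are known, not the source of the RNA here.

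The code was tested on simulated counts with the real means, depths and common dispersion, in 20 draws with 30 of 85 arms changed. For late against early, 64.0% of 2-fold and 99.7% of 8-fold changes were recovered and 1.7% of unchanged arms were called. For stage 6 against stage 5 these were 15.7%, 90.0% and 1.1%. Arms were drawn independently of each other, with rises and falls set at random. The rates therefore do not cover the dependence of the real fold changes on the scaling. A 4-fold change of the miR-309 cluster was found in 100% of draws and 1.7% of other lists were called. Hairpin positions came from an Ensembl annotation of dm6 and were matched by name. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The matching mRNA libraries that the series mentions were not used here.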

Results

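Small RNA libraries were made from Drosophila melanogaster embryos at 7 labelled stages of development, with 2 libraries per stage and 14 in all. The labels number the stages 1 to 7 and give their times as 160, 300, 530, 645, 930, 1160 and 1300 min, without saying from what point the minutes were counted. The measurement is the number of reads assigned to each mature miRNA arm (the 5p or 3p strand of a hairpin precursor). The table lists 466 arms, of which 251 had at least 1 count and 85 were abundant enough to test. Total counts per library ran from 17462 in stage 6 replicate 1 to 72507 in stage 7 replicate 1, so 1 count in the shallowest library equals 57.3 CPM (counts scaled to the library total). The labels do not say whether the 2 libraries of a stage came from separate embryo collections, so p-values measure the spread between these samples, which may be technical. The reads carry no molecular identifiers. Intervals cover counting error only, and floors cover that of the group with no count.

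A few arms made up most of every library. miR-286-3p, a product of the miR-309 cluster that is switched on in the blastoderm and helps to clear maternal mRNA, took 64.5% ± 1.14 of counts in stage 1 (SD, n = 2), 58.2% ± 1.21 in stage 3, 33.99% ± 5.21 in stage 4, 11.4% ± 1.78 in stage 6 and 15.9% ± 9.49 in stage 7, where it was again the top arm of replicate 2 (22.6%). bantam-3p, a growth-promoting miRNA, went from 1.67% ± 0.133 in stage 1 to 6.98% ± 1.37 in stage 4, 18.1% ± 0.284 in stage 6 and 16.1% ± 6.16 in stage 7. miR-8-3p, known from epithelia, went from 0.204% ± 0.0191 to 6.39% ± 3.42, 14.9% ± 0.0122 and 12.4% ± 3.69 over the same stages. miR-10-5p (3.02% ± 0.590 in stage 1, 12.1% ± 3.05 in stage 6 and 10.4% ± 0.821 in stage 7) and miR-263a-5p (0.350% ± 0.0312, 8.23% ± 0.0489 and 10.5% ± 2.11) completed the 5 arms with the highest mean CPM over all 14 libraries. miR-92b-3p came next (58308 CPM, against 60914 for miR-263a-5p) and in stage 1, at 10.5% ± 0.0776, stood above all of these but miR-286-3p. Shares of one library sum to a whole, so the share of every other arm moves when miR-286-3p falls. Fold changes below use TMM factors, which ranged from 0.595 in stage 1 replicate 1 to 1.57 in stage 5 replicate 2.

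**Figure D1:**
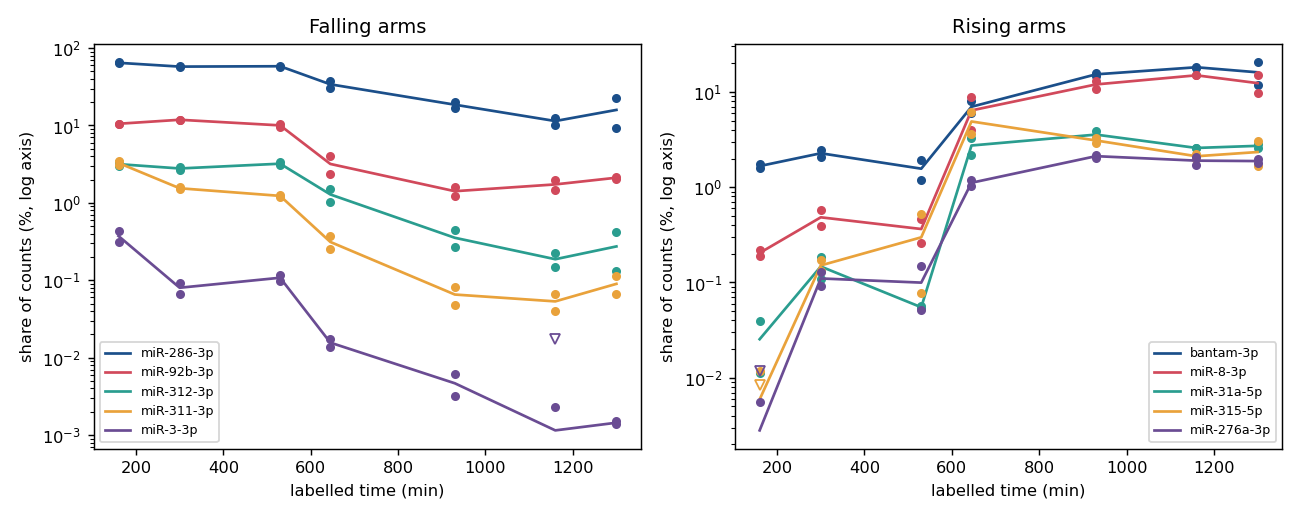
Share of counts (percent, log axis) of 5 arms that fell (left) and 5 that rose (right) against the labelled time in minutes. Each filled point is 1 library, lines join the stage means with zeros included, and open triangles mark libraries with no count, drawn at the level of 3 counts. miR-286-3p stood at 64.5% in stage 1, 11.4% in stage 6 and 15.9% in stage 7, and bantam-3p at 1.67%, 18.1% and 16.1%.

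The first question of a time course is which miRNAs change at all. Among the 85 tested arms, 69 differed among the 7 stages (edgeR quasi-likelihood F-test, Benjamini-Hochberg adjusted p below the threshold), and DESeq2 called 68. Of the 69, 15 had their highest stage mean in stage 1, 6 each in stages 2 and 3, 3 in stage 4, 8 in stage 5, 15 in stage 6 and 16 in stage 7. The strongest evidence for change came from miR-311-3p (adjusted p = 2.38e-10) and miR-92b-3p (adjusted p = 8.61e-10), which were both highest in stage 1. miR-995-3p and miR-11-5p, made from introns of Cdk2 and of E2f1, genes of cell cycle entry, led the group highest in stage 2, and miR-92a-3p and miR-6-3p the group highest in stage 3. The more abundant arm of the miR-11 hairpin, miR-11-3p (11546 counts against 1560), did not pass the same edgeR test (adjusted p = 0.0551). miR-315-5p and miR-124-5p were highest in stage 4, miR-31a-5p and miR-14-5p in stage 5, miR-8-3p and bantam-3p in stage 6, and miR-276a-3p and miR-263a-5p in stage 7. The stage of the highest mean depended on the scaling for some arms, 10 of the 69 with DESeq2 size factors and 11 with library size alone. With library size alone miR-92b-3p was highest in stage 2, with DESeq2 size factors miR-995-3p, miR-92a-3p and miR-6-3p were highest in stage 1, and with either miR-276a-3p was highest in stage 5. With a mean count of at least 50 required, 39 arms were tested and 33 differed.

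The broad comparison set the 6 libraries of stages 5 to 7 (late) against the 6 of stages 1 to 3 (early). Of 85 arms, 43 were higher and 25 lower in late embryos. In 55 of these 68 the 6 late libraries did not overlap the 6 early ones. Chance would give this for 0.216% of arms if all libraries were independent. Libraries of one stage resemble each other, so the share by chance is larger than that. miR-284-5p, from a hairpin in the 3′ UTR of the octopamine receptor gene Octbeta2R (dm6 chromosome 3R, 12551515 to 12551614), had 1022 late counts and none in the early libraries. It was at least 139-fold higher against a floor of 3 counts over the early group (adjusted p = 7.82e-07). miR-956-3p had 2818 late counts and 1 early count, a ratio of 1152 with a 95% counting interval of 207 to 45502 (adjusted p = 4.79e-07). miR-277-3p, a regulator of amino acid catabolism, had 590 late counts and 1 early count, a ratio of 241 with an interval of 43.1 to 9539 (adjusted p = 6.15e-08). Stage 7 replicate 1 held most late counts of miR-284-5p and miR-956-3p: without it the bound of miR-284-5p was 67.98-fold and the ratio of miR-956-3p was 625. Without the library that held the only early count, miR-956-3p was at least 322-fold (without stage 2 replicate 1) and miR-277-3p at least 70.6-fold higher (without stage 1 replicate 2).

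Other large rises were of arms with no early count. miR-927-5p and miR-927-3p, from a hairpin in an intron of mmd on the X chromosome, were at least 44.95-fold and 18.8-fold higher, miR-957-3p at least 43.2-fold, miR-375-3p at least 20.6-fold and miR-87-5p at least 14.3-fold. miR-276b-3p (log2 fold change 5.89 ± 0.631, SE) and miR-316-5p (5.74 ± 0.643) rose from 27.0 ± 44.0 and 20.5 ± 25.3 CPM (SD, n = 6) to 1575 ± 346 and 1388 ± 331 CPM. Among abundant arms, miR-31a-5p rose by 4.66 ± 0.280 on the log2 scale, miR-276a-3p by 4.90 ± 0.330, miR-8-3p by 4.31 ± 0.246 and bantam-3p by 2.19 ± 0.194. Without stage 1 replicate 1 the fitted values of miR-276b-3p and miR-276a-3p became 7.04 and 6.34, and without stage 3 replicate 1 that of miR-316-5p became 7.20; each time the stage was left with no count of the arm. miR-276a and miR-276b, the miR-281 copies, and miR-92a and miR-92b are close in sequence, and the division of reads between such relatives is uncertain.

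The falls were led by miR-3-3p of the miR-309 cluster, with a log2 fold change of -6.80 ± 0.441 (adjusted p = 5.34e-11). It was followed by miR-311-3p (-5.70 ± 0.294) and miR-310-3p (-4.95 ± 0.514) of the miR-310 cluster, by miR-275-3p (-4.60 ± 0.357), and by miR-312-3p (-4.50 ± 0.304) and miR-313-3p (-4.40 ± 0.878), which are also of the miR-310 cluster. miR-92a-3p (-3.90 ± 0.324) and miR-92b-3p (-3.62 ± 0.2004) share the host gene jigr1 on chromosome 3R, where miR-92a lies in an intron (25646506 to 25646600) and miR-92b in a 3′ UTR exon (25651398 to 25651497). miR-92b-3p went from 10.8% ± 0.872 of counts to 1.75% ± 0.374 (SD, n = 6). miR-4-5p (-3.14 ± 0.544) and miR-4-3p (-3.08 ± 0.371) completed the 10 largest falls. The order of these depended on single libraries. Without stage 6 replicate 2, miR-3-3p had -7.59 and miR-4-5p -4.59, without stage 6 replicate 1 miR-310-3p had -5.80, and without stage 7 replicate 2 miR-313-3p had -5.42, where again the stage was left with no count of the arm. miR-4-5p also had -3.74 without stage 5 replicate 2 and -3.80 without stage 7 replicate 2.

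The balance of rises and falls depended on the scaling. DESeq2 size factors moved the median log2 fold change of the 85 arms by 0.45 and library size alone by 0.97, and with library size alone 54 arms were higher and 20 lower (73.0% higher, against 63.2% with TMM). DESeq2 gave 45 higher and 24 lower. Restricting the test to the 39 arms with a mean count of at least 50 gave 16 higher and 18 lower (47.1% higher). In this setting the log2 fold changes also moved, by a median of -0.73 against the main fit. The balance of 16 to 18 therefore reflects a change of scale as well as the choice of arms.

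Groups of miRNAs were then compared between late and early embryos with fry, which asks whether the members of a list move one way on balance and does not compare the list with other miRNAs. All 11 lists with at least 2 tested arms passed. When the lists were instead compared with the other arms by camera, 3 passed with a preset correlation (the miR-309, miR-310 and miR-306/79/9 clusters) and none with an estimated correlation.

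All 7 tested arms of the miR-309 cluster fell, over all arms and adjusted over the list alone. The cluster holds 8 hairpins within 1059 bp of chromosome 2R (19660716 to 19661774, minus strand, outside protein-coding genes on that strand). Its share of counts went from 64.2% ± 3.76 early to 16.8% ± 5.87 late (SD, n = 6), and besides miR-286-3p (-2.97 ± 0.214) the fall took in miR-5-5p (-2.18 ± 0.234) and miR-6-3p (-2.31 ± 0.233). The fry adjusted p was 7.01e-06, and with an estimated correlation the camera adjusted p = 0.398. In the miR-310 cluster, whose members miR-310 to miR-313 lie within 509 bp of chromosome 2R (20583752 to 20584260), 4 of 5 tested arms fell over all arms and 5 adjusted over the list alone. Its share went from 5.20% ± 1.15 to 0.360% ± 0.147 (fry adjusted p = 1.69e-06; camera adjusted p = 0.330 with an estimated correlation).

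The 4 tested arms of the miR-306/79/9 cluster, encoded in an intron of the checkpoint kinase gene grp on chromosome 2L, also fell (fry adjusted p = 2.22e-05; camera adjusted p = 0.419 with an estimated correlation). miR-9c-5p changed by -2.51 ± 0.254, miR-9b-5p by -2.70 ± 0.355, miR-9b-3p by -1.62 ± 0.357 (not past the threshold with library size alone, -0.64) and miR-306-5p by -1.87 ± 0.395. Of the K-box seed family, whose members share a target motif, 3 of 8 tested arms fell and 5 did not pass, with the same counts adjusted over the list alone. The 3 were miR-6-3p, which also belongs to the miR-309 cluster, miR-11-5p (-1.53 ± 0.284), which is a passenger arm without that seed and did not pass with library size alone (-0.55), and miR-2b-3p (-0.67 ± 0.233, -0.23 and not past the threshold with DESeq2 size factors, 0.30 with library size alone). miR-2b-3p also did not pass in DESeq2, without a filter or with stages 6 and 7 against 1 and 2. Members were matched by hairpin, so the list also holds the 5p arms miR-2b-2-5p and miR-2c-5p, neither of which passed. The test of the list is therefore not confined to arms with the seed. The most abundant member, miR-11-3p (-0.23 ± 0.209), and the less abundant miR-2a-3p (0.05 ± 0.255) did not pass, and other settings called each of them in both directions. miR-11-3p passed as lower with a mean count of at least 50 (-0.99, adjusted p = 0.000166) and without stage 7 replicate 2 (-0.41, adjusted p = 0.0363), and as higher with library size alone (0.75, adjusted p = 0.00123). miR-2a-3p passed as higher with library size alone (1.01, adjusted p = 0.00114), DESeq2 size factors (0.49, adjusted p = 0.0483) and DESeq2 (0.49, adjusted p = 0.0179), and as lower with a mean count of at least 50 (-0.70, adjusted p = 0.0252). fry put this list on the falling side (adjusted p = 0.000875) and on the rising side with library size alone (adjusted p = 0.0195), and the camera adjusted p = 0.528 with an estimated correlation.

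Several lists named for tissues rose. Both tested muscle arms were higher late, miR-1-3p by 3.26 ± 0.803 and miR-133-3p by 2.74 ± 0.411 (fry adjusted p = 7.01e-06; camera adjusted p = 0.528 with an estimated correlation). In the nervous system list 3 of 4 tested arms rose, namely miR-315-5p (4.39 ± 0.439), miR-1000-5p (3.83 ± 0.770) and miR-87-5p, while miR-124-5p had 0.45 ± 0.550 and did not pass (fry adjusted p = 0.000157; camera adjusted p = 0.528 with an estimated correlation). miR-124-5p passed with library size alone (1.37, adjusted p = 0.0261), and without 1 library its value ran from 0.095 to 1.59. In the edgeR test among all stages it did differ (adjusted p = 0.000347), with its highest mean in stage 4, which late against early leaves out. The arm named 3p, the usual guide of miR-124, had 57 counts over all libraries and was not tested. The value of miR-315-5p was 6.03 without stage 1 replicate 2 and 4.99 without stage 3 replicate 2, and that of miR-1000-5p 5.18 without stage 2 replicate 1. Among 10 tested epithelial and gut arms, 7 rose and 3 fell. miR-8-3p, miR-31a-5p and miR-281-2-5p (1.81 ± 0.304) were among the rises, and the 3 falls were miR-275-3p, miR-305-3p and miR-305-5p, whose hairpins are neighbours (fry adjusted p = 0.000187; camera adjusted p = 0.650 with an estimated correlation). Counts adjusted over each of these lists alone were the same.

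In the Hox-cluster list 3 of 4 tested arms rose, miR-993-3p by 3.602 ± 0.486, miR-10-3p by 1.02 ± 0.223 and miR-10-5p by 0.49 ± 0.167, and miR-iab-4-5p had -0.01 ± 0.446 (fry adjusted p = 0.000715; camera adjusted p = 0.646 with an estimated correlation). Without stage 1 replicate 1, which held its only counts in that stage, miR-993-3p had 5.04. The call of miR-10-5p ended without stage 4 replicate 1 (0.31, adjusted p = 0.102) or stage 5 replicate 1 (0.41, adjusted p = 0.0506), and its sign turned with a mean count of at least 50 (-0.22), a setting that also ended the calls of miR-10-3p (0.32) and miR-283-5p (0.47). Both tested arms of the miR-12 cluster, in an intron of Gmap on the X chromosome, rose, miR-12-5p by 2.16 ± 0.396 and miR-283-5p by 1.18 ± 0.273 (fry adjusted p = 4.57e-05; camera adjusted p = 0.528 with an estimated correlation). The sensory organ list split, with 2 of 7 arms higher, 1 lower and 4 not past the threshold. miR-263a-5p rose by 1.72 ± 0.173, miR-996-3p changed by -1.23 ± 0.336 (not past the threshold with library size alone, -0.25, or without a filter, -0.88), and miR-9a-5p (-0.25 ± 0.214) and miR-279-3p (-0.26 ± 0.280) did not pass. With a mean count of at least 50 both passed as lower, miR-9a-5p at -0.99 (adjusted p = 0.000329) and miR-279-3p at -1.02 (adjusted p = 0.00327), and with library size alone both passed as higher, at 0.71 (adjusted p = 0.00319) and 0.73 (adjusted p = 0.0173). For this list fry pointed up (adjusted p = 0.00835) and the mean was 0.59, while the median was -0.25 and camera pointed down (adjusted p = 0.650 with an estimated correlation).

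The remaining lists had fewer than 2 tested arms, and fry was not run on them. The let-7 complex, known from the larva to pupa transition, had 52 counts in all 14 libraries and no tested arm. Of the cluster of miR-277, miR-34 and miR-317 only miR-277-3p, one of the largest rises, was tested, and the whole cluster had 715 late and 2 early counts. Testis-enriched clusters had 1 tested arm (miR-982-5p, 0.44 ± 0.602) and mirtrons, which are spliced introns, 1 (miR-1010-3p, -0.23 ± 0.329). Neither passed, but with library size alone both passed as higher, at 1.38 (adjusted p = 0.0359) and 0.74 (adjusted p = 0.0381). Without 1 library the value of miR-982-5p ran from 0.066 to 1.87 and that of miR-1010-3p from -0.42 to 0.11.

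**Figure D2:**
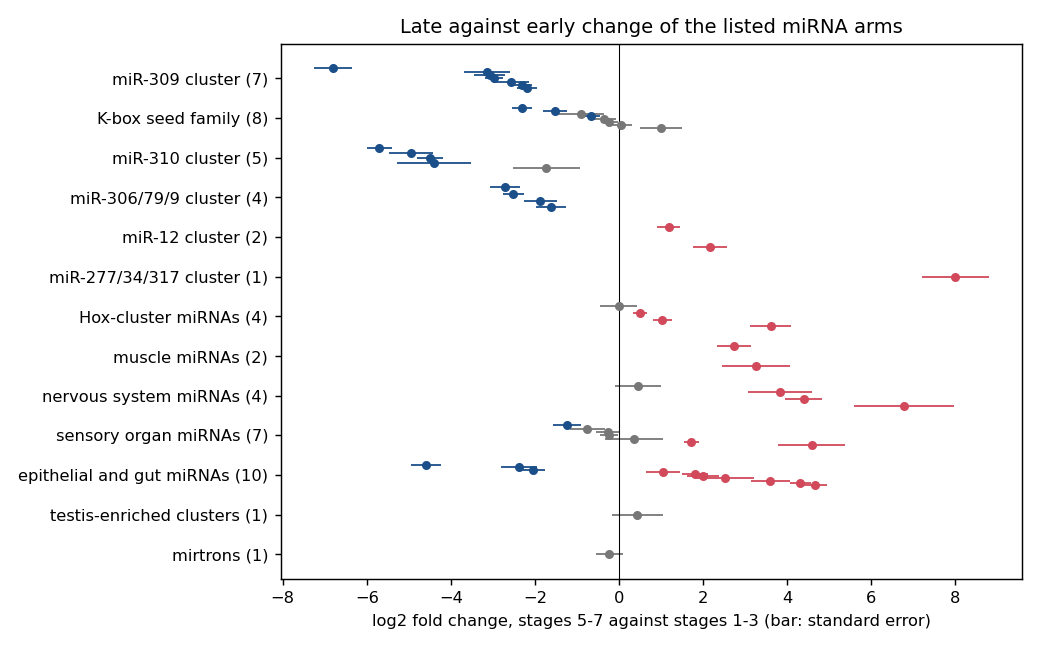
Log2 fold change of stages 5 to 7 against stages 1 to 3 (horizontal axis) for each tested arm of the lists (rows, number of tested arms in brackets). Points are edgeR estimates with bars of 1 standard error, red for higher, blue for lower and grey for not past the threshold; the value of miR-87-5p, with no early count, depends on the prior count. All 7 arms of the miR-309 cluster lie left of 0, from -6.80 to -2.18; with library size alone as scaling the K-box list turned to the rising side.

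The title of the series names evolutionary strategies of miRNA regulation, so arms of families shared among bilaterian animals were set against the rest. The 29 tested arms of these families had a median log2 fold change of 1.05 from early to late, against 0.02 for the other 56. Among the shared families 18 arms rose, such as miR-8-3p and miR-263a-5p, and 7 fell, such as miR-92b-3p. The difference of 1.03 was not distinguished from chance (permutation test over arms, two-sided, p = 0.360), and setting the 6 arms with no count in one group to their bounds left both medians where they were. Arms are not independent replicates, so the test describes these miRNAs. fry placed the list on the rising side (adjusted p = 6.80e-05), and the camera adjusted p = 0.601 with an estimated correlation.

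Neighbouring stages were compared to place the changes in time. Between stages 1 and 2, 13 arms rose and 2 fell in edgeR, while in DESeq2 12 rose and 9 fell. The smallest edgeR adjusted p was that of miR-263a-5p, which went from 211 to 1504 counts (log2 fold change 2.47 ± 0.312, adjusted p = 1.63e-05). miR-276a-3p went from 2 to 73 counts (adjusted p = 0.000115). miR-1002-3p (44 counts in stage 2), miR-263a-3p (22) and miR-968-5p (17) had no count in stage 1 and were at least 11.4-fold, 5.68-fold and 4.39-fold higher, against a floor of 3 counts over stage 1. The hairpins of miR-1002 and miR-968 are neighbours on chromosome 2L (13747609 to 13747697 and 13747748 to 13747839). Without 1 library of stage 1 these bounds ran from 1.99-fold to 6.22-fold, and without stage 2 replicate 2 that of miR-968-5p was 2.23-fold. miR-3-3p changed by -2.49 ± 0.527 (adjusted p = 0.00183) and miR-311-3p by -1.31 ± 0.412 (adjusted p = 0.0293). Leaving out either library of stage 1 reduced the 15 calls to 8 and ended those of miR-311-3p, miR-263a-3p and miR-968-5p. The call of miR-311-3p also ended without either library of stage 2, with library size alone (adjusted p = 0.0510) and without a filter (adjusted p = 0.151). That of miR-263a-3p also ended without stage 2 replicate 1 (adjusted p = 0.0918), with DESeq2 size factors (adjusted p = 0.0612) and with counts thinned to the shallowest library (adjusted p = 0.0665), and that of miR-968-5p without stage 2 replicate 2 (adjusted p = 0.102). Fitting the 2 stages alone raised the calls to 32.

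No arm passed between stages 2 and 3 in edgeR. At an unadjusted p under 0.05 there were 14 arms, and DESeq2 called 1 higher and 1 lower.

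The largest step was from stage 3 (530 min) to stage 4 (645 min), with 16 arms higher and 14 lower in edgeR and 25 higher and 11 lower in DESeq2. miR-31a-5p went from 0.0550% ± 0.00155 to 2.74% ± 0.825 of counts (SD, n = 2), miR-8-3p from 0.364% ± 0.146 to 6.39% ± 3.42 and miR-315-5p from 0.298% ± 0.313 to 4.90% ± 1.80. miR-87-5p, miR-958-3p and miR-277-3p had no count in stage 3 and 27, 21 and 21 in stage 4, at least 4.01-fold, 3.12-fold and 3.12-fold higher. Without 1 library of stage 3 these bounds ran from 1.41-fold to 2.19-fold, and without stage 4 replicate 2 miR-87-5p and miR-277-3p had 1 count each. miR-3-3p changed by -3.67 ± 0.594 (adjusted p = 0.000104), miR-311-3p by -2.83 ± 0.437 (adjusted p = 6.91e-05) and miR-310-3p by -2.73 ± 0.717 (adjusted p = 0.00547; -3.58 without stage 4 replicate 1 and -2.07 without stage 4 replicate 2). The 30 calls became 19 without stage 3 replicate 1 or without stage 4 replicate 2. Each of those omissions ended the calls of miR-87-5p, miR-958-3p, miR-277-3p and miR-310-3p, the first 3 of which also ended without stage 3 replicate 2, with the 2 stages alone or with thinned counts. Without stage 6 replicate 2 the calls of miR-87-5p (adjusted p = 0.0553) and miR-958-3p (adjusted p = 0.0511) ended, and without stage 6 replicate 1 that of miR-87-5p (adjusted p = 0.0533).

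From stage 4 to stage 5, 5 arms rose and 7 fell in edgeR, and 9 rose and 9 fell in DESeq2. miR-284-5p rose by 4.30 ± 1.12 on the log2 scale (adjusted p = 0.0138) and miR-927-5p by 3.78 ± 0.905 (adjusted p = 0.00988), and miR-957-3p went from 1 to 16 counts, a ratio of 21.1 with an interval of 3.28 to 885. miR-275-3p (-2.61 ± 0.578), miR-311-3p (-2.51 ± 0.460) and miR-312-3p (-2.17 ± 0.478) led the falls. The values moved with the library of stage 4 left out. Without replicate 1 they were 3.71 for miR-284-5p, 5.22 for miR-927-5p and -1.81 for miR-275-3p. Without replicate 2 they were 8.47 for miR-284-5p, then with no count in stage 4, and 2.72 for miR-927-5p, and miR-957-3p was at least 2.22-fold higher. The number of calls also rested on single libraries: it was 2 without stage 4 replicate 1 and 1 without stage 5 replicate 1. The calls of miR-284-5p, miR-957-3p, miR-275-3p and miR-312-3p ended in both cases, that of miR-284-5p also in DESeq2 (adjusted p = 0.152), that of miR-957-3p also without the other library of either stage, with thinned counts, and without stage 4 replicate 1 and stage 7 replicate 2 together, and that of miR-927-5p ended without stage 4 replicate 2 or stage 5 replicate 1.

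No arm passed from stage 5 to 6 or from stage 6 to 7 in edgeR, and DESeq2 called 0 in both. At an unadjusted p under 0.05 there were 4 and 1 arms. In simulated counts for stage 6 against stage 5, 15.7% of 2-fold changes and 90.0% of 8-fold changes were recovered, so 2-fold changes at that step would mostly go undetected. Stage 7 against stage 6 was not simulated.

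**Figure D3:**
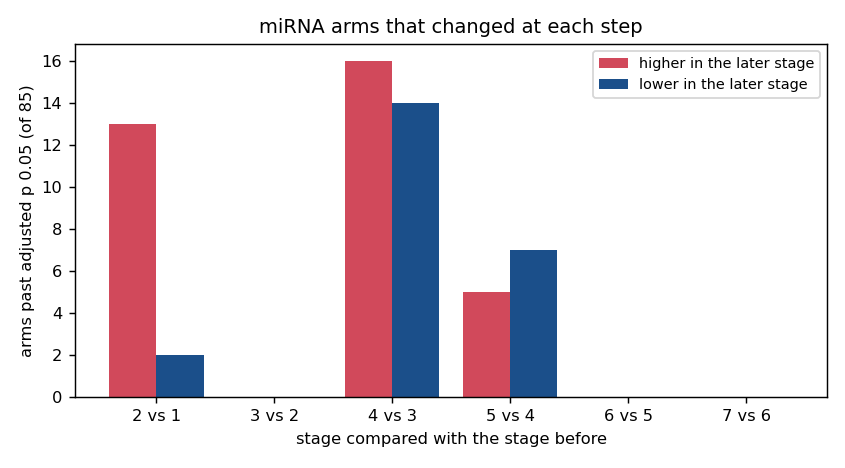
Number of miRNA arms (of 85 tested) past the adjusted p threshold between each stage and the one before (horizontal axis), higher in red and lower in blue. Values are from edgeR. Stage 4 against stage 3 has 16 higher and 14 lower (25 and 11 in DESeq2), and 3 of the 6 steps have 0, of which DESeq2 called 1 higher and 1 lower for stage 3 against stage 2 and 0 for the other two.

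Between the ends of the series, stage 7 against stage 1, 43 arms were higher and 22 lower. miR-956-3p, miR-284-5p and miR-968-5p had no count in stage 1 and 1839, 714 and 332 in stage 7, at least 134-fold, 52.1-fold and 24.2-fold higher. Most stage 7 counts of miR-956-3p and miR-284-5p were in replicate 1. Without it miR-956-3p was at least 19.7-fold and miR-284-5p at least 8.34-fold higher, without stage 7 replicate 2 at least 223-fold and 86.0-fold, while miR-968-5p was at least 34.2-fold and 16.4-fold higher in these cases, and without 1 library of stage 1 the 3 bounds ran from 10.96-fold to 73.4-fold. miR-3-3p went from 234 to 2 counts, a ratio of 0.00187 with a counting interval of 0.000225 to 0.00683, and miR-311-3p changed by -6.14 ± 0.509 (adjusted p = 1.14e-08) and miR-310-3p by -5.28 ± 0.805 (adjusted p = 1.55e-05; -5.98 without stage 7 replicate 2). Of the 65 arms, 63 were also called late against early, all in the same direction; both comparisons use stages 1 and 7.

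Libraries of one stage resembled each other. Spearman correlations of log2 CPM across the 85 arms (arms are not independent replicates) ran from 0.886 to 0.975 within stages, against a median of 0.675 between stages. In 9 of 14 libraries the closest library was of the same stage, all 8 libraries of stages 1 to 4 among them, and the other 5 were of stages 5 to 7 with their closest library in stage 6 or 7. The lowest agreement was in stage 4 (0.886) and stage 7 (0.897).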

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

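The count of arms called late against early was 67 to 69 with 1 library left out and 66 to 74 with the other scalings, DESeq2, stages 6 and 7 against 1 and 2, and the settings chosen after seeing the data (2 libraries left out, thinning, removal of miR-286-3p); the rises kept to 41 to 44 and the falls to 25 or 26 over the libraries left out. A mean count of at least 50, where fewer arms are tested, gave 34 calls late against early, with 16 rises, 33 among all stages, 29 for stage 7 against stage 1, 9 for stage 2 against stage 1 and 7 for stage 5 against stage 4; without a filter more arms are tested and 66 rose late against early. Of the arms highest in stages 1 to 3 there were 27, 17 with the mean count of at least 50, and 23 to 28 over the libraries left out. For stage 2 against stage 1, 32 arms were called with the 2 stages alone and 8 to 16 over the libraries left out, with 8 without either library of stage 1. For stage 4 against stage 3 the range was 19 to 35, with 19 without stage 3 replicate 1 or stage 4 replicate 2, and for stage 5 against stage 4 it was 1 to 17, with 2 without stage 4 replicate 1 and 1 without stage 5 replicate 1. Stage 3 against stage 2 gave 1 call without a filter or with the 2 stages alone, 2 in DESeq2, 9 without stage 4 replicate 1 and stage 7 replicate 2, and 0 to 1 over the libraries left out (1 without either stage 7 library). Stage 6 against stage 5 gave 1 without a filter or without those 2 libraries, 3 with the 2 stages alone and 0 to 1 over the libraries left out (1 without either library of stages 1, 4 or 7), and stage 7 against stage 6 gave 0 to 1 (1 without stage 7 replicate 1). Of the 11 lists, 3 passed camera with the preset correlation and 0 with the estimated one, which compare a list with other arms; the sensory organ list then pointed down (adjusted p = 0.646 and 0.650), and the K-box list pointed up with library size only (adjusted p = 0.0195). The bilaterian difference did not pass under any setting run (0.82 to 1.62 over the libraries left out). For the named arms, 1728 of 1844 refits kept the direction and side of the threshold, 61 lost and 12 gained the call, and 43 turned sign. The 12 gained calls were miR-11-3p as lower with a mean count of at least 50, without stage 7 replicate 2 and without the 2 libraries, miR-9a-5p and miR-279-3p as lower with a mean count of at least 50 and without the 2 libraries, miR-2a-3p as higher with DESeq2 size factors, library size only and DESeq2, and miR-124-5p and miR-982-5p as higher with library size only. Of the 43, 5 passed the threshold in the new direction: miR-11-3p, miR-9a-5p, miR-279-3p and miR-1010-3p as higher with library size only (adjusted p = 0.00123, 0.00319, 0.0173 and 0.0381) and miR-2a-3p as lower with a mean count of at least 50 (adjusted p = 0.0252). All 43 were of miR-11-3p (0.21 with DESeq2 size factors, 0.75 with library size only, 0.11 without a filter, 0.21 in DESeq2, 0.12 with stages 6 and 7 against 1 and 2), miR-9a-5p (0.19, 0.71, 0.080 and 0.19 in the first 4 of these), miR-279-3p (0.19, 0.73, 0.081, 0.19 and 0.094, and 0.055 when thinned), miR-1010-3p (0.22, 0.74, 0.090, 0.22 and 0.12, 0.18 when thinned, and -0.42 to 0.11 without 1 library), miR-iab-4-5p (0.42, 0.96, 0.34 and 0.43, and -0.31 to 0.51 without 1 library), miR-2a-3p (-0.70 with a mean count of at least 50, -0.24 without the 2 libraries, -0.051 when thinned, -0.072 with miR-286-3p removed, -0.14 to 0.18 without 1 library), miR-2b-3p (0.30 with library size only), miR-10-5p (-0.22 with a mean count of at least 50) and miR-263a-3p (-0.51 when thinned, -1.03 to 0.62 without 1 library). Some settings moved the tested arms as a set. The median shift late against early was 0.45 on the log2 scale with DESeq2 size factors and 0.97 with library size only. It was 0.34 without a filter and -0.73 with a mean count of at least 50. miR-11-3p, miR-9a-5p and miR-279-3p moved by similar amounts in these settings. Other causes of the changes were not tested. Depth limits the rare arms: 3 counts are 172 CPM in the shallowest library and 41.4 CPM in the deepest.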

Other observations

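The tests in this part were all chosen after the data had been seen, and the decision limits of the wrong-label test were revised after a first version had been run. The number of arms detected grew with development. At an equal depth of 17462 counts, early libraries were expected to show 91.3 ± 7.70 arms and late ones 129 ± 3.78 (SD, n = 6), a difference of 37.7 (exact permutation test over 924 splits, two-sided, p = 0.00216, the smallest it can give). With miR-286-3p removed and 9184 counts drawn, the values were 95.7 ± 7.05 and 114 ± 1.27 (exact p = 0.00216). The effective number of arms, the exponential of the Shannon entropy, was 6.17 ± 0.844 early and 17.1 ± 0.526 late (exact p = 0.00216). All of these exact tests take single libraries as independent. Their 924 splits part the 2 libraries of a stage, which resemble each other. The exact p-values are therefore too small for a comparison of stages, and no test with stages kept whole was run.

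The arm shares of miR-14 changed with the stage. miR-14-5p made up 43.2% of miR-14 reads in stages 4 and 5 (582 of 1348, exact interval 40.5 to 45.9) and 10.7% in the other stages (332 of 3116, 9.59 to 11.8). Stages 4 and 5 were singled out because the share was high there, the library lowest among them had 29.2% (exact interval 22.2 to 37.1), and the highest of the other 10 libraries had 22.3% (18.7 to 26.2). The ratio of pooled shares was 4.05, against a median of 1.31 and a highest value of 2.06 (bantam-5p) among the 10 other hairpins with at least 150 counts on each arm. In 7 of these 10 the share of the rarer arm was also higher in stages 4 and 5, such as miR-8-5p (4.58% against 2.35%). Some kept nearly the same share. miR-305-5p made up 21.6% in stages 4 and 5 and 21.1% in the others, and miR-4-5p 13.9% and 14.7%. For miR-124, a neuronal miRNA whose 3p arm is the usual guide, 449 counts fell on the 5p arm and 57 on the 3p arm over all libraries, and for miR-34, whose usual guide is the 5p arm, 5 fell on the 5p and 58 on the 3p arm. Whether the annotation behind the table named the arms of these hairpins the usual way round was not tested, so the values given for miR-124-5p hold for the arm so named. The same holds for other hairpins, among them miR-284 and miR-87, of which only the 5p arm was tested. miR-1-3p, abundant in fly muscle, had 125 counts in all.

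The 2 libraries of stage 4 and the 2 of stage 7 differed more than those of other stages. Across the 85 arms, the difference of replicate 2 from replicate 1 in stage 4 followed the change from stage 3 to stage 5 (Spearman rho 0.538, Pearson r 0.564, permutation p = 1e-04, the smallest 10000 permutations can give), and in stage 7 it ran against the change from stage 4 to stage 6 (rho -0.483, r -0.584, permutation p = 1e-04). Arms are not independent. In stages 3, 5 and 6 the rho was 0.02, -0.19 and -0.24, but with a different axis, stages 6 and 7 minus stages 1 and 2, leaving out the stage itself. Those values are therefore not a like comparison for stages 4 and 7, and stages 1 and 2 were not examined. Low depth as the cause is argued against by well-counted arms. Over arms with at least 1000 counts in both libraries the median absolute log2 ratio was 0.461 in stage 4 (8 arms) and 0.460 in stage 7 (12 arms), against 0.262 and 0.151 in stages 5 and 6. A candidate explanation is that embryos in one library of each pair were less far along, stage 4 replicate 1 and stage 7 replicate 2.

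That stage 7 replicate 2 is a library of stage 4 or 5 under a wrong label cannot be told apart from slower progress. Of 16 arms above every stage 4 and 5 library in both stage 6 libraries and in stage 7 replicate 1, 50% were also above them in stage 7 replicate 2 (8 arms, exact interval 24.7 to 75.3, 20% by chance). A first version of the test, which asked only whether the interval lay above chance, would have set the wrong label aside; arms that move together make the interval too narrow for that. Of 10 arms below every stage 4 and 5 library in those 3 libraries, 2 were also below them in stage 7 replicate 2. Its Spearman correlations were 0.946 with stage 6 replicate 2, 0.924 with stage 5 replicate 2, 0.897 with stage 7 replicate 1 and 0.722 and 0.808 with the stage 4 libraries, and the closest library of stage 5 replicate 2 was also stage 6 replicate 2 (0.952). The miR-14-5p share speaks against the wrong label: it was 4.66% (exact interval 3.44 to 6.15) in stage 7 replicate 2 and 29.2 to 52.7% in the stage 4 and 5 libraries. It is a single hairpin, singled out for its share in those stages, and the share was also below that of stage 7 replicate 1 (13.8%) and of both stage 6 libraries (17.5% and 22.3%), where slower progress would not put it. The label therefore stays open. Without stage 4 replicate 1 and stage 7 replicate 2, 72 arms were called late against early.

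Within the miR-310 cluster, miR-311-3p fell ahead of its neighbour miR-312-3p up to stage 4. The log2 ratio of their counts was 0.05 ± 0.00419 in stage 1, -0.85 ± 0.0253 in stage 2, -1.38 ± 0.0194 in stage 3 and -2.04 ± 0.0129 in stage 4 (SD, n = 2). It was then -2.44 ± 1.07 in stage 5, -1.82 ± 0.0964 in stage 6 and -1.43 ± 0.615 in stage 7, near the level of stage 3 again, with as few as 7 counts of miR-311-3p in a library. The change from stage 1 to stage 3 was -1.43 with a counting error of 0.0709, too large for counting noise. How multiply matching reads were assigned is not known, so reads counted for the wrong neighbour stay open, and different decay or processing of the 2 miRNAs may be involved; neither was tested.

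Of 100 assignments of the 14 libraries to the stages, 1 gave as many late against early calls, the real one with 68, and the highest other gave 61. For the lists it was also 1, with 11 lists against 10 at most. This sets aside only a chance assignment of single libraries, which parts the libraries of a stage that resemble each other, and the median of the other assignments was 0 calls. With the libraries of a stage kept together, 70 groupings set 3 stages against 3 with 1 left out. Of these, 4 gave at least 68 calls, the real one included, with 71 at most; the other 3 set stages 5 to 7 against 3 of stages 1 to 4. For the lists 12 of the 70 gave all 11, the most there can be. The counts therefore do not single out the division at stage 4 among groupings of whole stages.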
